A study of Mus musculus with 3 samples.

How the data were processed

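The sources were 3 droplet-based 10x Genomics single-cell RNA libraries of mouse knee synovium and infrapatellar fat pad, 1 each from control mice, mice at 1 week and mice at 2 months after surgical destabilisation of the medial meniscus (DMM). Per the labels, each library pooled the tissue of 5 to 10 mice, which was digested in 0.25% trypsin for 30 min and then in collagenase I at 300 U/mL for 30 min, and live cells were sorted before loading. The sex of the mice, the hour of harvest, the sequencing runs and a sham operation were not given in the sources used here.

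The deposited matrices held UMI counts per gene and cell barcode, whole numbers without normalisation. Per the file headers they were written by Cell Ranger 5.0.0 for the control and 1-week libraries and 5.0.1 for the 2-month library, whereas the processing notes of the submitters name version 6.0.1 and build mm10. The files held 9003, 13986 and 10799 barcodes with 96782789, 179561680 and 159333121 UMIs in the control, 1-week and 2-month libraries. Of 32285 genes, 32235 were located in the GENCODE vM21 annotation of GRCm38. So were 454 of 454 genes looked up singly, which were the named genes, the list members with the largest ratios and a few others. The interferon gene Mx1 was not in the files.

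Barcodes with at least 500 genes and at most 10% mitochondrial UMIs passed, 8099, 12316 and 9782 cells. Doublets were called with Scrublet in scanpy 1.11.5 within each library (357, 509 and 432 calls, or 4.41%, 4.13% and 4.42%) and removed. That left 7742, 11807 and 9350 cells with medians of 3129, 3423 and 3525 genes and 1.77%, 3.52% and 3.41% mitochondrial UMIs. Counts were log-normalised to 10000 per cell and genes present in at least 10 cells were kept. The 3 libraries were then clustered together without batch correction on 3000 variable genes other than mitochondrial, ribosomal, haemoglobin, Xist and Y-linked genes, scaled and clipped at 10 standard deviations, with 30 principal components, 15 neighbours and Leiden resolution 1.0. Immune cells were clustered again in the same way, and so were mesenchymal cells, there without cell-cycle genes. The software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.

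Clusters were named by fixed marker sets for 29 broad classes and 6 mesenchymal subclasses. A set's score was the mean log2 ratio of marker CPM in the cluster to a baseline, the percentile 20 over clusters, with 20 CPM added, and at least 3 markers had to be detected. A marker was detected at 20 CPM or more and at least 2-fold over the baseline. A cluster took the name of its best class unless another class had more markers among its 10 leading genes, and only when its own markers led there by 2 or the next class scored under 0.8 of the best. Shallow clusters also needed a leading marker. Erythroid cells were those with over 10% haemoglobin UMIs. Dividing cells were assigned to the nearest cluster of a named class, found without cell-cycle genes. The thresholds of this naming rule and the assignment of dividing cells were set after the clusters had been seen, and the markers, gene lists, filters, clustering settings, gene rule and 16 alternative settings were fixed before the data were examined.

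Expression in a class was the sum of raw UMIs over its cells in a library, given as CPM, the UMIs scaled to a common total of the class. A class was compared only where both libraries held at least 50 of its cells. With 1 library per group no test between groups was possible, so values are given with exact 95% intervals for counting error, Poisson for CPM, Clopper-Pearson for shares and conditional binomial for ratios. Mesenchymal sums held 62737564, 99777800 and 103705242 UMIs, macrophage sums 7996350, 16995140 and 8492900, endothelial sums 8422385, 17352872 and 11385926, and pericyte and smooth muscle sums 5693811, 8805108 and 5784329. The median log2 ratio of all genes in mesenchymal cells was 0.02 in each comparison, and in macrophages -0.06 at 1 week and 0.01 at 2 months against the control. When 1 sum was 0 the ratio was computed against a floor of 3 UMIs over the class sum and given as a bound.

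Named genes were those with the largest CPM ratios among genes with at least 200 UMIs in the 2 sums together and at least 20 CPM in 1 or more libraries, the lower sum being raised to 3 UMIs where it was below that. The 12 highest and 12 lowest were taken for mesenchymal cells against the control, 6 and 6 between the operated libraries, and 5 and 5 for subclasses, macrophages and endothelial cells. Mitochondrial, ribosomal and haemoglobin genes, Xist and Y-linked genes, predicted and clone-named genes, antigen receptor segments and markers of other classes were left out of the naming. For each of 30 gene lists the median log2 CPM ratio was taken over members with at least 50 UMIs and placed among 10000 random lists of the same size, drawn with a fixed seed from 20 bins of expression. These percentiles describe the libraries and are not tests. The lists whose medians the text gives were chosen after the medians and the alternatives had been seen, and the numbers outside the central 95% are given over all lists.

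Free RNA from mesenchymal cells was estimated from the level of the fixed mesenchymal markers, as a share of the mesenchymal level, at 1.79%, 2.49% and 1.99% in macrophages and 3.91%, 3.29% and 2.53% in endothelial cells of the control, 1-week and 2-month libraries. Shares of cells with a UMI of a gene were taken after thinning each cell to 2000 UMIs, and cells below that depth were left out. Thinned mesenchymal cells had medians of 1008, 1020 and 1013 genes.

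The settings fixed beforehand were a lenient filter (at least 200 genes, at most 20% mitochondrial), a strict filter (at least 1000 genes, at most 5%), doublets kept, Leiden resolutions 0.5 and 2.0, centring and scaling within each library, TMM scaling in edgeR, a denominator without mitochondrial, ribosomal and haemoglobin genes, equal weight for every cell, list members with at least 200 UMIs, no abundance filter with 0.5 UMI added, weights of the control's subclass composition, subclasses found from control cells alone, subclusters found without the list genes, thinning to 1000 UMIs and no thinning. Another 4 settings were chosen after seeing the data. They left bone and marrow cell types out of the denominators, left the subclass markers and list genes out of the subclustering, left out cells with an Xist UMI, or subtracted the mesenchymal profile from macrophage and endothelial sums.

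The genes differing in 4 classes at once, the clock genes and the collagen part were noticed in the data. Genes of that kind were at least 2-fold apart with 2 CPM added in each of mesenchymal, macrophage, endothelial and pericyte and smooth muscle cells, with at least 30 UMIs. The counting interval was applied to the bound for female mice only after the point value had been seen. The procedure was tested on simulated data, mesenchymal sums of 12530 genes in which 200 were set to differ. There the interval held the true ratio for 95.6% of the unchanged genes and excluded 1 for 100% of those set 2-fold and 4-fold apart, whose median ratios were 1.98 and 4.02. Of the genes named by the rule, 12 of 12 on each side had been set 4-fold apart. Among 30 unchanged lists 2 lay outside the central 95%, and a list set 2-fold higher had a median of 0.94 at percentile 100. The simulated counts carried counting error only, drawn for each gene independently. They had no spread between mice or libraries and no change of cell mix. The simulation therefore checked the calculation and cannot show how the intervals or percentiles behave with such spread. Neutrophil sums and classes with fewer than 50 cells in a library were left out of the comparisons of genes in the text.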

Results

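Single-cell RNA libraries of mouse synovium and infrapatellar fat pad were compared between control mice and mice with surgical destabilisation of the medial meniscus (DMM), a model of post-traumatic osteoarthritis. The question for each comparison was how the cell makeup and the transcripts of the joint lining tissue differed from the control at 1 week and at 2 months after the operation, and between these times. There were no replicates: each of the 3 groups was 1 library of live-sorted cells pooled from 5 to 10 mice. After filtering, 7742 control cells, 11807 cells at 1 week and 9350 cells at 2 months were kept, with a median of 10667, 12721 and 13293 UMIs per cell. All intervals below are 95% intervals that cover counting error only, not the spread between mice. The control mice were harvested at 2 months of age and the operated mice had surgery at that age, so the 2-month group was also older. Whether the control mice had a sham operation, the sex of the mice and the hour of harvest were not given in the sources used here.

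Fibroblast-like mesenchymal cells, which build and lubricate the joint lining, made up most of the cells in the control (57.9%, 95% interval 56.8 to 59.0, 4484 cells) and 2-month (62.9%, 61.9 to 63.9, 5879 cells) libraries and 48.9% (48.0 to 49.8, 5771 cells) of the 1-week library. Macrophage-like cells, the resident and recruited phagocytes of the tissue, were 13.6% (13.03 to 14.3, 1611 cells) of the 1-week library, 1.29 times (1.18 to 1.40) the control share of 10.6% (9.94 to 11.3, 822 cells), and 7.82% (7.28 to 8.38, 731 cells) of the 2-month library. Monocyte-like cells, the blood-derived precursors of recruited macrophages, numbered 5 in the control, 143 at 1 week and 48 at 2 months, a share 18.8 times (7.85 to 58.6) and 7.95 times (3.18 to 25.6) that of the control. Neutrophil-like cells were 1.06% (0.843 to 1.31) of control, 4.16% (3.81 to 4.53) of 1-week and 8.07% (7.53 to 8.65) of 2-month cells. One of their clusters had the marrow granulocyte-precursor markers Ltf, Ngp and Camp among its leading genes. It held 23 control, 159 1-week and 246 2-month cells, so marrow cells were not told apart from neutrophils of the tissue. The T-cell-like share was 4.36 times (2.94 to 6.69) the control share at 1 week, 193 cells against 29, and 0.628 times (0.344 to 1.13) at 2 months, 22 cells. Endothelial-like cells were lower in both operated libraries, at 11.9% (11.3 to 12.5) and 9.13% (8.56 to 9.74) against 14.0% (13.2 to 14.8), and the pericyte and smooth muscle-like share was 9.75% (9.10 to 10.4) in the control, 5.98% (5.56 to 6.42) at 1 week and 4.82% (4.40 to 5.28) at 2 months. Osteoclast-like, chondrocyte-like and granulocyte-precursor-like cells belong to bone, cartilage and marrow and enter the same denominators. They numbered 134, 110 and 101 at 1 week, 3, 64 and 110 at 2 months, and 1, 1 and 29 in the control. With libraries centred the chondrocyte-like ratio was 0.858 at 1 week and 0.731 at 2 months, so its direction is not settled. The mesenchymal and macrophage shares at 1 week lay on the other side of the control when clusters were made finer (ratios 1.02 and 0.966), so their direction is not settled here. Clusters without a name held 5.64%, 7.85% and 3.17% of the 3 libraries, mostly led at 1 week by the antigen-presentation genes Cd74 and H2-Ab1. Macrophage was the best-scoring class of the clusters that these genes led, so the macrophage shares leave such cells out.

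**Figure D1:**
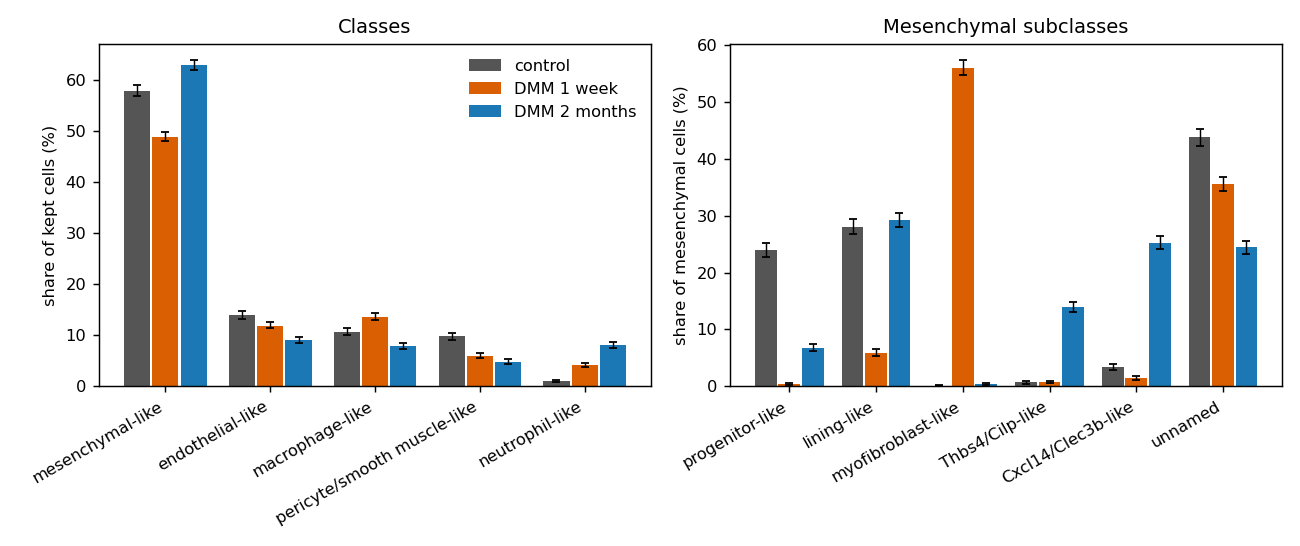
Shares of cell classes among kept cells and of mesenchymal subclasses among mesenchymal cells in each library. Bars give 95% binomial intervals for counting error only.

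Within the mesenchymal cells, those scored as synovial lining, the Prg4-rich surface layer, were 28.1% (26.8 to 29.4) in the control, 5.84% (5.25 to 6.48) at 1 week and 29.3% (28.1 to 30.4) at 2 months. Progenitor-like cells, scored by universal fibroblast progenitor genes such as Pi16 and Dpp4, were 23.97% (22.7 to 25.3), 0.433% (0.281 to 0.639) and 6.75% (6.12 to 7.42). Myofibroblast-like cells, scored by genes of the contractile matrix producers of wound repair, were 0.112% (5 cells) in the control, 56.1% (54.8 to 57.4, 3238 cells) at 1 week and 0.391% (23 cells) at 2 months. One of their clusters was led by the interferon genes Ifit1 and Isg15. Another, led by Ptn, Mmp13 and Cxcl5, held 66.7% of the myofibroblast-like cells at 1 week. Neither had a myofibroblast marker among its 10 leading genes. The cluster led by the contractile gene Acta2 held 15.9% of the 1-week mesenchymal cells, so most myofibroblast-like cells were not led by contractile genes. An unnamed cluster led by Col11a1, C1qtnf3 and Acan also scored best as myofibroblast. It held 26.98% of mesenchymal cells at 1 week, 0.153% at 2 months and 0 control cells. The 1-week share of 56.1% therefore depended on the naming rule. Cells like the Cxcl14 or Clec3b sublining were 3.32%, 1.39% and 25.3%, and cells like the Thbs4 or Cilp sublining were 0.691%, 0.710% and 13.9%. These are shares of cells whose transcripts matched a marker set, and the markers themselves differed between the libraries, so they are not abundances of fixed cell kinds. With each library centred and scaled alone, the progenitor-like shares were 21.9%, 3.10% and 12.95%, the lining-like shares 27.6%, 9.88% and 22.2%, and the myofibroblast-like shares 0.264%, 26.4% and 0.712%. With the marker and list genes left out of the clustering, the same shares were 24.4%, 0.381% and 6.99%, then 28.1%, 5.06% and 28.7%, then 0.0223%, 78.05% and 0.391%. The Cxcl14 or Clec3b sublining-like shares were 17.9%, 1.89% and 21.9% with libraries centred and 3.35%, 1.21% and 20.2% without the marker and list genes, and the Thbs4 or Cilp sublining-like shares 0.814%, 0.204% and 8.14%, then 0.758%, 0.918% and 22.5%. With the strict filter the Cxcl14 or Clec3b sublining-like share at 2 months was lower than in the control (ratio 0.289), so its direction is not settled. Unnamed clusters led by Myoc, by Fst and by Inmt also scored best for this subclass and held mostly control cells. They were 13.6%, 23.9% and 4.91% of control mesenchymal cells, and 0.204%, 0.272% and 0.306% at 2 months. The control share of 3.32% therefore depended on the naming rule. With coarser clusters the progenitor-like ratio to the control was 0.0433 at 2 months, and over the 11 settings, the main one among them, it ran from that value to 0.642. Unnamed mesenchymal cells were 43.8%, 35.5% and 24.4%, and adding the unnamed clusters led by Pi16 and Cd34 to the progenitor-like cells gave 24.2%, 3.62% and 14.95%. In 14 of 20 mesenchymal clusters, with 72.0% of the cells, at least 80% came from 1 library.

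Mesenchymal cells at 1 week held far more transcripts of wound-matrix and cartilage-type matrix genes than control mesenchymal cells. Tnn, coding for the matrix protein tenascin-W, was at 362 CPM (UMIs scaled to the class total of the library; 359 to 366) against 0.271 (0.158 to 0.434), and Mmp13, a collagenase that degrades cartilage collagen, was at 277 (274 to 280) against 0.701 (0.510 to 0.942), a ratio of 395 (294 to 544). C1qtnf3, a secreted adipokine-like protein, was at 769 against 2.87 CPM, 268-fold higher (232 to 312). The fibrillar collagen gene Col11a1 was 206-fold higher (172 to 248), Col12a1, which codes for a fibril-associated collagen, was 65.3-fold higher (60.3 to 70.8), and the imprinted growth genes Mest and H19 were 95.5-fold (82.8 to 111) and 81.4-fold (74.6 to 88.9) higher. The neutrophil-attracting chemokine gene Cxcl5 was at 74.8 CPM against 2 UMIs in the control, a ratio of 2346 (649 to 19375). Kcnj15, Megf6, Glipr1 and Fbn2 completed the 12 genes with the highest ratios among 6039 eligible genes. Several of these genes also led 1-week clusters of myofibroblast-like and unnamed cells, so the class sums partly describe which cells the class held.

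On the lower side at 1 week, Scg3, coding for a secretory granule protein, was at 0.872 CPM against 174, 200-fold lower (162 to 250), and the B-cell chemokine gene Cxcl13 was 230-fold lower (157 to 353). The complement gene C7 was 70.6-fold lower (57.5 to 87.7), the extracellular protein gene Myoc was at 12.8 against 703 CPM, 54.7-fold lower (51.7 to 57.9), and Pcolce2, which codes for an enhancer of procollagen processing, was at 34.9 against 767 CPM, 21.9-fold lower (21.2 to 22.7). Inmt, Gpr1, Alkal2, Gldn, Vit, Lmo2 and Ppl were the other lower genes. Tnn (ENSMUSG00000026725) lies on chromosome 1 from 160085029 to 160153580 of build GRCm38, Mmp13 (ENSMUSG00000050578) on chromosome 9 from 7272514 to 7283331, Scg3 (ENSMUSG00000032181) on chromosome 9 from 75643189 to 75684056, and Myoc (ENSMUSG00000026697) on chromosome 1 from 162639155 to 162649693.

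Gene groups at 1 week gave a picture of repair, matrix and division. The contractile and myofibroblast genes, which give repair fibroblasts their pull and their matrix, had a median log2 ratio of 2.24 over 16 genes, above all 10000 random lists matched on expression (percentile 100), with 13 at least 2-fold higher. Within this list Cthrc1 was at 1437 CPM against 25.7, Postn at 2502 against 99.3 (25.2-fold higher, 24.6 to 25.8) and Tnc at 289 against 5.93. Collagen-making genes had a median of 1.30 (percentile 100, 24 of 25 higher), with the cross-linking enzyme gene Lox 14.4-fold higher (13.8 to 15.1) and Col1a1 5.24-fold higher (5.21 to 5.27), and 3 of this list's genes also served as mesenchymal markers. Genes of cartilage-associated matrix had a median of 2.47 (percentile 100, 9 of 16 at least 2-fold higher). The cartilage proteoglycan gene Acan was at 283 CPM against 3 UMIs in the control, a ratio of 5918 (2025 to 28700). Whether cartilage or bone entered the dissections was not given in the sources used here, so the cartilage values may include such tissue. Matrix-degrading enzyme and inhibitor genes had a median of 0.90 (percentile 100, 10 of 22 at least 2-fold higher), with Mmp14 5.42-fold higher (5.32 to 5.53), and proliferation genes a median of 2.37 (percentile 100, 23 of 23 higher). Cells scored as cycling were 7.69% of mesenchymal cells at 1 week, 0.290% in the control and 0.765% at 2 months. Interferon-response genes, the antiviral and alarm programme of the cell, had a median of 1.48 (percentile 100, 14 of 15 higher), with Ifit1 4.82-fold higher (4.42 to 5.27).

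Other groups were lower at 1 week. Complement genes had a median of -0.82 (percentile 0.065, 12 of 13 lower), with C3, the central complement component, at 166 CPM against 638. Adipogenesis and lipid genes had a median of -0.78 (percentile 0.01, 17 of 21 lower), with the adipocyte hormone gene Adipoq at 0.531 CPM against 10.9. An unnamed mesenchymal cluster led by Cfd, Car3 and Adipoq held 21 control cells and 2 at 1 week. Free RNA from adipocytes was not tested in mesenchymal cells. Genes of BMP and GDF signalling, which steer skeletal cell fate, had a median of -1.31 (percentile 0, 8 of 15 at least 2-fold lower), with Gdf10 4.85-fold lower (4.53 to 5.19), and neurotrophic and axon-guidance genes a median of -1.03 (percentile 0.01, 7 of 13 at least 2-fold lower), with the nerve growth factor family gene Ntf3 24.8-fold lower (19.2 to 32.5). The lubrication list stayed inside the central 95% of random lists (median 0.11, percentile 59.7), although Prg4, which codes for the lubricant lubricin, was at 8344 CPM against 48490 (5.81-fold lower, 5.80 to 5.83) and the hyaluronan synthase gene Has1 was 5.82-fold lower (5.70 to 5.93). Cytokine and chemokine genes had a median of -0.20 (percentile 4.59) with 7 genes at least 2-fold higher and 9 lower. Genes of the tissue-dissociation stress response were lower in 21 of 21 cases (median -0.71, percentile 0.01). Of the 30 lists, 10 lay above and 7 below the central 95% of random lists.

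At 2 months the mesenchymal cells also held higher levels of repair and matrix-degradation genes than the control, at smaller ratios. Tnn was at 20.9 CPM against 0.271, 77.3-fold higher (48.2 to 133), and Mmp13 was 42.5-fold higher (31.6 to 58.6). Tnc, coding for the injury-associated matrix protein tenascin-C, was at 113 against 5.93 CPM (95% interval of the ratio 17.1 to 21.1), and Slpi, an inhibitor of neutrophil proteases, was 19.3-fold higher (17.2 to 21.7). The acute-phase gene Saa3 was 9.68-fold higher (8.76 to 10.7), the cell-cycle inhibitor gene Cdkn2a 9.58-fold higher (8.17 to 11.3), and Dbp, a clock-output transcription factor gene, 9.57-fold higher (8.68 to 10.6). Hp, C1qtnf3, Cthrc1, Edil3 and Nt5dc2 completed the higher genes among 5845 eligible genes. Lower were Scg3 (12.5-fold, 11.8 to 13.2), the fatty-acid carrier gene Fabp4 at 14.8 against 88.3 CPM (5.95-fold, 5.63 to 6.30), Myoc at 165 against 703 CPM (4.26-fold, 4.18 to 4.33) and the interferon-induced gene Ifi27l2a at 39.2 against 158 CPM. Scrg1, Alkal2, Stmn4, Col4a5, Rarres1, Adam23, Sox11 and Rbp4 were the other lower genes.

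The gene groups at 2 months gave a mixed picture. Matrix-degrading genes had a median of 0.56 (percentile 100, 15 of 22 higher), with the protease gene Mmp3 2.92-fold higher (2.85 to 2.99) and its inhibitor gene Timp1 3.14-fold higher (3.08 to 3.19). Contractile genes had a median of 0.54 (percentile 100, 6 of 16 at least 2-fold higher), collagen-making genes 0.30 (percentile 100, 21 of 25 higher) with Lox 3.01-fold higher (2.87 to 3.15), and cartilage-associated genes 1.04 (percentile 100, 7 of 13 at least 2-fold higher) with Fmod, a collagen-binding proteoglycan gene, 2.43-fold higher (2.34 to 2.54). The cartilage median was -0.60 when each library was weighted to the control's mix of subclasses, so its direction depended on that mix. Interferon-response genes were lower (median -0.54, percentile 0, 13 of 15 lower), with Isg15 at 15.2 CPM against 41.6. Adipogenesis genes had a median of -0.55 (percentile 0, 15 of 20 lower), with Adipoq 12.6-fold lower (10.1 to 15.9). The unnamed mesenchymal cluster led by Cfd, Car3 and Adipoq held 0.468% of control and 0.867% of 2-month mesenchymal cells. Free RNA from adipocytes was not tested here, so values of adipocyte genes may include it. BMP and GDF genes had a median of -0.52 (percentile 0, 13 of 16 lower). Cytokine and chemokine genes had a median of -0.31 (percentile 0.01, 16 of 24 lower), while proliferation genes lay slightly higher (0.30, percentile 99.3, 18 of 23 higher), with medians from 0.06 to 0.85 over 14 settings. Complement genes had a median of -0.25 (percentile 1.60), with Cfd, the fat-cell complement protease gene, at 2.52 against 75.7 CPM. This complement median had the other sign (0.32) when every cell was given equal weight. Neurotrophic genes (0.27, percentile 96.1) and lubrication genes (-0.10, percentile 22.8) stayed inside the central 95%, and stress-response genes were lower (-0.55, percentile 0). Of 30 lists, 6 lay above and 13 below.

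Between the 2 operated libraries, the 1-week repair genes were lower at 2 months and several genes low at 1 week were higher. Mest was 80.5-fold lower (72.6 to 89.4), Col11a1 50.1-fold lower (46.8 to 53.8), and H19, Nrk, Capn6 and C1qtnf3 followed among 5952 eligible genes. Cxcl13 was at 29.9 CPM against 0.261, 115-fold higher (78.1 to 176), C7 was 58.3-fold higher (47.5 to 72.3), and Inmt, Smpd3, Hmcn2 and Vit completed that side. Proliferation genes were lower in 23 of 23 cases (median -2.18), collagen-making genes in 25 of 25 (-0.85), contractile genes in 15 of 16 (-1.73) and interferon-response genes in 14 of 15 (-2.17), each at percentile 0. Cartilage-associated genes (-2.11, percentile 0) and cytokine genes (-0.58, percentile 0) were also lower. The cartilage-associated median ran from -2.33 to -0.322 over 14 settings, so its size is not settled. Complement genes (0.80), BMP and GDF genes (0.91) and neurotrophic genes (1.01) were higher, each at percentile 100. Matrix-degrading (-0.21, percentile 7.52), adipogenesis (0.25, percentile 96.4) and lubrication genes (-0.18, percentile 21.8) stayed inside the central 95%, and stress-response genes were higher (0.24, percentile 99.3). Of 30 lists, 5 lay above and 11 below.

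Per cell, with each cell thinned to 2000 UMIs, a Prg4 UMI was found in 96.7% of control, 44.1% of 1-week and 84.3% of 2-month mesenchymal cells. Endothelial cells, in which lubricin is not made at such levels, gave 95.2%, 27.9% and 66.3%, so free Prg4 RNA in the droplets adds to these shares. Postn, a matrix gene of repair fibroblasts, was found in 10.7%, 82.0% and 16.7% of mesenchymal and 0.857%, 14.8% and 0.717% of endothelial cells. The progenitor gene Dpp4 was found in 9.18%, 1.06% and 5.45% of mesenchymal cells and in 0.214%, 0.0722% and 0 of 837 endothelial cells. Mki67, a gene of dividing cells, was found in 0.317%, 3.81% and 0.553% of mesenchymal and 0.536%, 5.12% and 1.67% of endothelial cells. Before thinning the median depth of these cells was 13140, 16019 and 15786 UMIs in mesenchymal and 7136, 10426 and 11742 in endothelial cells. Cells below 2000 UMIs were left out, 72, 17 and 97 of the mesenchymal and 148, 18 and 17 of the endothelial cells.

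**Figure D2:**
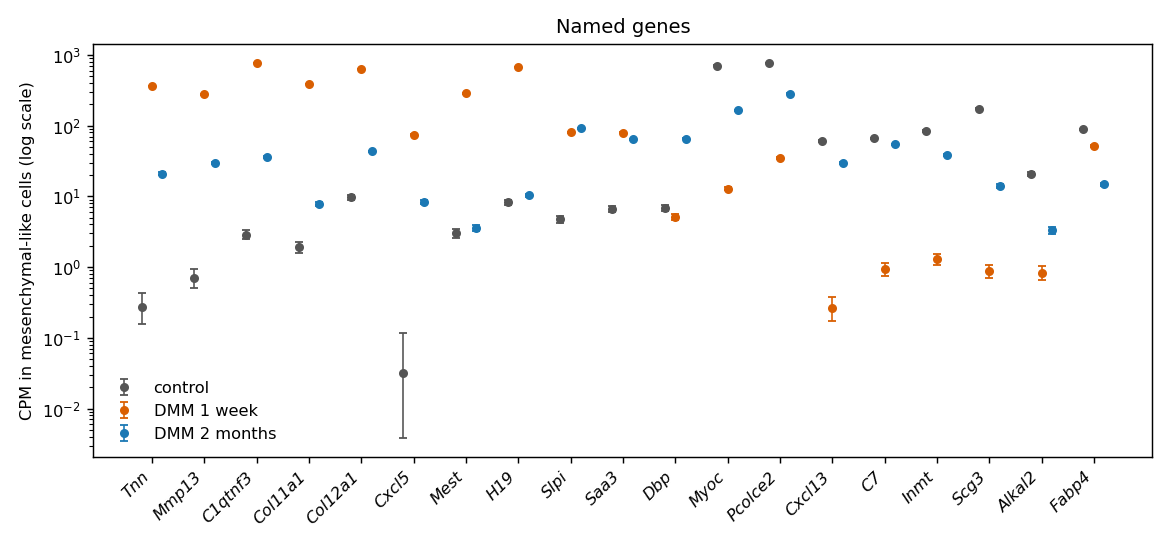
CPM of a selection of the named genes in mesenchymal cells of the control, 1-week and 2-month libraries, on a log scale. Bars give 95% intervals for counting error only.

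Among synovial lining-like cells, Hp, Ccn5 and Emb were among the highest genes in both operated libraries. Hp, which codes for the acute-phase protein haptoglobin, was at 77.4 CPM at 1 week against 0.594, 130-fold higher, and 131-fold higher (76.4 to 246) at 2 months. Ccn5, a matricellular growth regulator gene, was 69.4-fold (58.3 to 83.3) and 62.1-fold (52.4 to 74.3) higher, and Emb was 44.6-fold and 38.8-fold higher. The T-cell chemokine gene Ccl5 was 173-fold higher (78.5 to 474) and Slpi, a leading gene of the cluster that held most lining-like cells after surgery, 48.2-fold higher at 1 week. Ccl5 also led a T-cell-like cluster with 141 cells at 1 week and 4 in the control. Free RNA from those cells was not tested, so the Ccl5 value may include it. At 2 months the olfactory receptor gene Olfr810 (38.3 CPM against 1 UMI, ratio 838, 150 to 33117) and Cilp (20.9-fold) were also higher. Lower were Neurl3 (23.9-fold at 1 week and 8.14-fold at 2 months), Nrn1l (18.7-fold and 17.5-fold) and Tspan7 (10.2-fold and 14.5-fold), together with Krtdap and Lmo2 at 1 week and Fxyd6 and Adam23 at 2 months. The control lining-like cells lay mostly in another cluster (71.0% in one) than those at 1 week (90.5% in a different one) and 2 months (68.3% in the latter), so part of these ratios may describe what the clusters separated.

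Progenitor-like cells could be compared only at 2 months (397 cells against 1075), since the 1-week library held 25. Phex, a mineralisation regulator gene of bone cells, was at 57.2 against 1.17 CPM, 48.7-fold higher (29.5 to 86.3), the Wnt modulator gene Sfrp2 was 10.6-fold higher (9.06 to 12.5) and Lox 6.56-fold higher (5.28 to 8.19), with Pltp and Cmah also higher. Scg3 was 32.9-fold lower, followed by Ptgir, Cilp, Stmn2 and Necab1. Scg3 also led the cluster that held 51.9% of the control progenitor-like cells, whereas 90.4% of those at 2 months lay in another cluster. Sfrp2 was lower and not higher (ratio 0.243) with coarser clusters, and Cilp was not lower (ratio 1.08) with libraries centred. In Cxcl14 or Clec3b sublining-like cells, the pentraxin gene Ptx3 was 19.8-fold higher (12.7 to 32.3) at 1 week, followed by Emb, Postn, Ccl7 and AY036118, and Rbp4, Ccn2, Fmo2 and Atf5 were lower. Prg4 was also lower there, but free Prg4 RNA from other mesenchymal cells was not separated from it. At 2 months Cxcl13 was at 167 against 5.43 CPM, 30.8-fold higher (14.9 to 76.6), followed by Aldh1a2, Cxcl9, Dbp and Ampd3, and Barx1, Meox1, Arhgdib, Matn2 and Fmo2 were lower. Fmo2 also led the cluster that held 81.2% of the control cells of this subclass, and Cxcl13 was among the 10 leading genes of the other cluster, which held 52.5% of the cells at 1 week and 71.0% at 2 months, so part of these values describes what the clusters separated. Cxcl13 was lower (ratio 0.379) with libraries centred. Fmo2 at both times and Arhgdib and Matn2 at 2 months also lay on the other side of the control under at least 1 setting.

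Macrophages of the 1-week library held far fewer transcripts of resident-macrophage genes and more of lipid-associated ones. The hyaluronan receptor gene Lyve1 was at 28.2 CPM against 2218, 78.7-fold lower (71.8 to 86.3), the complement receptor gene Vsig4 24.4-fold lower (22.8 to 26.0) and the efferocytosis receptor gene Timd4 43.7-fold lower (32.5 to 60.0), and the resident list had a median of -2.02 (percentile 0, 13 of 17 lower). Lipid-associated genes had a median of 0.87 (percentile 100, 15 of 17 higher), with Spp1, coding for osteopontin, at 2668 against 22.3 CPM, 120-fold higher (103 to 140), and Gpnmb 43.4-fold higher (33.1 to 58.0). Monocyte-derived genes had a median of 0.90 (percentile 100, 5 of 11 at least 2-fold higher; -0.0181 with coarser clusters, so the direction of this list is not settled), with the monocyte-homing receptor gene Ccr2 10.5-fold higher (8.90 to 12.4). Thbs1, coding for the matricellular protein thrombospondin-1, was at 195 against 1.75 CPM, 112-fold higher (66.4 to 204), Arg1, an arginine-metabolising enzyme of repair macrophages, at 34.4 CPM against 1 UMI (ratio 275, 49.1 to 10871), Itgax at 32.8 CPM against 2 UMIs (ratio 131, 36.2 to 1087) and Sema4d 85.6-fold higher (39.2 to 234). H19 was also among the 5 highest, but its level was 1.87 times what free mesenchymal RNA would give. The alternative-activation gene Retnla was at 12.2 against 1486 CPM, 122-fold lower (106 to 141), Cd209d had 3 UMIs at 1 week (312-fold lower, 106 to 1521), and the heat-shock genes Hspa1b and Hspa1a and Sema6a were 69.9-fold, 53.2-fold and 66.6-fold lower. Interferon-response genes had a median of 1.42 (percentile 100, 13 of 15 higher), with the interferon regulator gene Irf7 7.62-fold higher (6.63 to 8.79). A cluster led by Rsad2, Irf7 and Ifit3 held 176 of the 1611 macrophages at 1 week and 1 in the control, and the median was 0.65 with coarser clusters. Class II antigen-presentation genes had a median of 0.74 (percentile 99.5, 7 of 7 higher). Unnamed clusters led by the class II gene H2-Eb1 and by Cd74 scored best as macrophages but were left out of these sums. They held 422 and 182 cells at 1 week, 3 and 53 in the control and 23 and 83 at 2 months. The class II and Ccr2 values of macrophages therefore describe only the named cells. Inflammatory macrophage genes were lower as a group (median -1.14, percentile 0, 12 of 16 lower), although Ptgs2, the inducible prostaglandin synthase gene, was 14.2-fold higher (10.9 to 18.8) and the cytokine gene Il1b 7.67-fold higher (6.88 to 8.58). Proliferation genes had a median of 1.54 (percentile 100) and stress-response genes -1.42 (percentile 0, 21 of 21 lower). Of 29 lists, 13 lay above and 8 below.

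At 2 months the macrophages held part of the same pattern. Spp1 was at 792 CPM, 35.6-fold higher (30.6 to 41.5) than in the control, Gpnmb 16.9-fold higher (12.8 to 22.7), and the lipid-associated list had a median of 0.87 (percentile 100, 15 of 17 higher). The B-cell chemokine gene Cxcl13 was 19.7-fold higher (11.6 to 36.5), Thbs1 18.4-fold higher (10.8 to 34.03), the gelatinase gene Mmp9 13.6-fold and the kinase gene Fgr 10.1-fold higher. Hal, coding for a histidine-degrading enzyme, had 3 UMIs against 164 CPM, 464-fold lower (158 to 2252), and the interferon-induced gene Isg15 was at 29.8 against 248 CPM, 8.32-fold lower (7.29 to 9.52), with Hspa1a, Dlg4 and Hspa1b also lower. Resident genes were lower (median -0.44, percentile 0, 12 of 17 lower), with Timd4 3.80-fold lower (3.31 to 4.37), and monocyte-derived genes higher (0.72, percentile 100), with Ccr2 7.42-fold higher (6.26 to 8.87). Interferon-response genes were lower in 13 of 13 cases (median -0.96, percentile 0), class II genes higher in 7 of 7 (0.48, percentile 99.6), and inflammatory macrophage genes lower (-0.75, percentile 0). Proliferation genes lay above (0.40, percentile 99.9, but -0.00138 with coarser clusters) and stress-response genes below (-0.46, percentile 0). Of 28 lists, 9 lay above and 12 below, and in 9 of 9 macrophage clusters at least 80% of the cells came from 1 library, so cell state and library could not be separated.

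Endothelial cells at 1 week held more transcripts of vessel basement membrane and sprouting genes and fewer of adipogenesis and lipid genes. Col18a1, coding for a basement membrane collagen, was at 806 against 93.0 CPM, 8.67-fold higher (8.07 to 9.33), Col15a1 was 4.43-fold higher (4.19 to 4.67), and the basement membrane list had a median of 1.49 (percentile 100, 12 of 13 higher). Sprouting genes had a median of 0.97 (percentile 100, 6 of 13 at least 2-fold higher), with the adhesion gene Mcam 4.25-fold higher (3.88 to 4.67), and proliferation genes 2.35 (percentile 100, 17 of 23 at least 2-fold higher). The neuropeptide gene Nts was at 44.4 CPM against 1 UMI (ratio 374, 66.9 to 14780), Glycam1, which codes for a lymphocyte-homing ligand of high endothelial venules, at 28.2 CPM against 1 UMI (ratio 238, 42.5 to 9413), and Chga, a neuroendocrine granule gene, was at 24.03 CPM against 0 UMIs, at least 67.5-fold higher at a floor of 3 UMIs, with a 95% lower limit of 54.6. Nts was also among the 10 leading genes of a separate lymphatic endothelial-like cluster, with 0 control cells and 24 at 1 week. Free RNA from those cells was not tested. The immune checkpoint gene Cd276 was 45.8-fold higher (27.7 to 82.1), while C1qtnf3 was at 1.01 times the level that free mesenchymal RNA would give. Timp4, an inhibitor of matrix proteases in capillaries, was at 0.980 against 164 CPM, 168-fold lower (104 to 289), the capillary carbonic anhydrase gene Car4 102-fold lower (58.0 to 199), and Penk and Slc28a2 followed. Pcolce2 was also among the 5 lowest, but its level was 1.18 times in the control and 0.752 times at 1 week what free mesenchymal RNA would give. Adipogenesis and lipid genes were lower in 16 of 16 cases (median -1.15, percentile 0), with the adipocyte gene Car3 at 2 UMIs against 40.8 CPM (354-fold lower, 97.4 to 2938), the lipoprotein lipase gene Lpl 11.5-fold lower (9.47 to 14.0) and the fatty-acid transporter gene Cd36 3.56-fold lower (3.41 to 3.71), and class II genes in 6 of 6 (-1.67, percentile 0), with Cd74 5.38-fold lower (4.89 to 5.92). Endothelial activation genes stayed inside the central 95% (percentile 18.2), and stress-response genes were lower (-1.24, percentile 0). Of 30 lists, 9 lay above and 8 below. The largest cluster of endothelial cells was a different one in each library, with 67.3% of control, 49.7% of 1-week and 53.2% of 2-month cells, so part of these values may describe what the clusters separated. Free RNA from adipocytes, which carry many genes of the lipid list, was not tested. Only 2 of 1404 endothelial cells at 1 week and 0 of 1081 in the control lay in a cluster of dividing cells. That count leaves out any dividing cells that stayed in the endothelial clusters. Without thinning a Mki67 UMI was found in 13.2% (185 of 1404) of endothelial cells at 1 week and 1.94% (21 of 1081) in the control.

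At 2 months basement membrane genes of endothelial cells were also higher (median 0.61, percentile 100, 11 of 13 higher), with Col18a1 3.15-fold (2.92 to 3.41) and Col15a1 2.97-fold (2.80 to 3.14) higher. Glycam1 was at 42.0 CPM against 1 UMI (ratio 354, 63.2 to 13995), and Hist1h1b, Cmah and Tacr1 were 9.86-fold, 8.93-fold and 6.84-fold higher. Gdpd3, a phospholipase gene, was at 1.76 against 136 CPM, 77.6-fold lower (50.01 to 128), followed by Eif3j2, Hspa1a, Gdf15 and the growth factor gene Igf2. Lipid genes were lower in 16 of 16 cases (-1.03, percentile 0), with Lpl 3.06-fold lower (2.67 to 3.52), and class II genes lower (-0.84, percentile 0). Sprouting (0.01, percentile 37.4) and activation genes (0.05, percentile 76.9) stayed inside the central 95%. Proliferation genes were slightly higher (0.34, percentile 99.5) and stress-response genes lower (-0.44, percentile 0). Of 30 lists, 3 lay above and 12 below. Hist1h1b and the proliferation median had the other sign (ratio 0.452 and median -0.15) with finer clusters. Gdpd3 (ENSMUSG00000030703) lies on chromosome 7 from 126766334 to 126775649 of the same build.

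**Figure D3:**
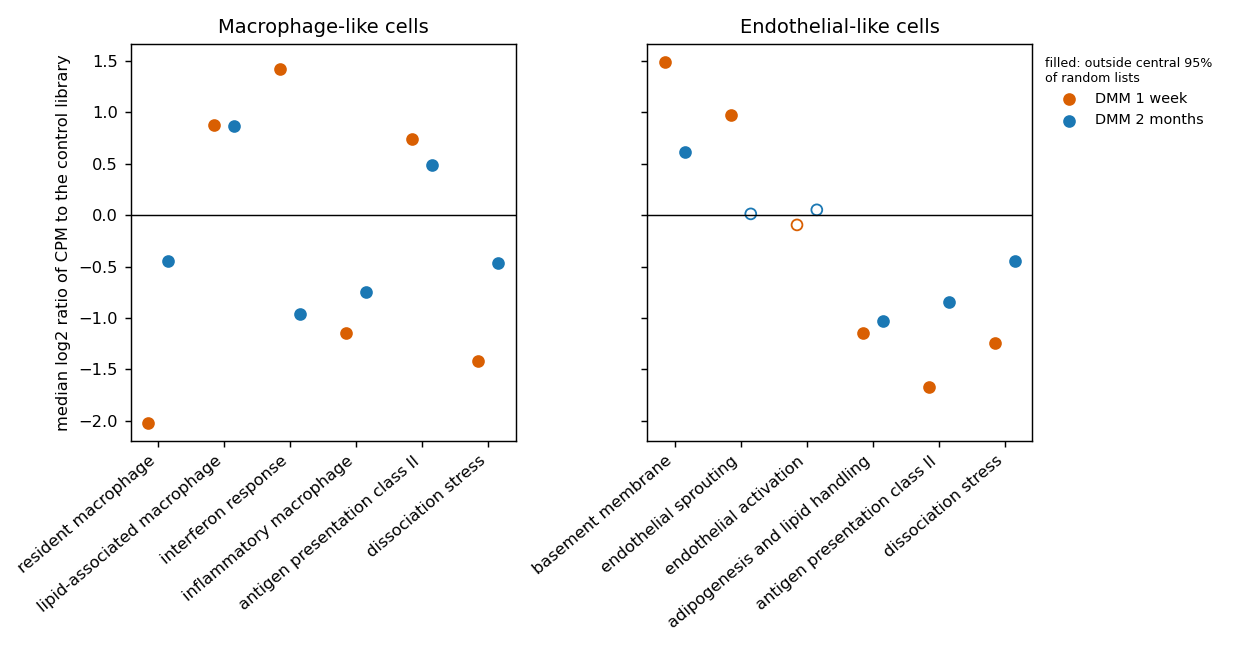
Median log2 CPM ratio of gene lists in macrophages and endothelial cells against the control. Filled points lie outside the central 95% of random lists of the same size and expression.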

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

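The tests of the Xist pattern were chosen only after it was seen, and between-time differences in the results listed last were not tested. In the 2-month library 7.07% of cells (661 of 9350, 95% interval 6.56 to 7.61) held 2 or more UMIs of Xist (ENSMUSG00000086503), the RNA that silences 1 X chromosome in female cells, against 0 of 7742 control and 0 of 11807 1-week cells. Free Xist RNA or index hopping over male cells was argued against, because a Y-linked UMI was found in 11.5% of these cells (76 of 661) and in 75.5% of the 2-month cells without Xist. Female mice in the pool may account for the pattern, but this remains open. Among cells with at least 5000 UMIs the Xist share was 7.81% in mesenchymal cells, 10.1% in macrophages, 7.20% in endothelial cells and 6.56% in pericytes and smooth muscle, but 2.38% (1.03 to 4.64, 8 of 336) in neutrophils, against 7.79% over all such cells. The sex of the animals was not given in the sources used here, and differences of the 2-month library from the others could include differences of sex.

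Several results lay on opposite sides of the control at the 2 times after surgery, some of them not under every setting. The mesenchymal share of cells was 0.844 times the control share at 1 week and 1.09 times at 2 months. For macrophages these ratios were 1.29 and 0.736. With finer clusters each lay on one side of the control at both times, mesenchymal at 1.02 and 1.23 and macrophages at 0.966 and 0.631. The Cxcl14 or Clec3b sublining-like share of mesenchymal cells was 0.417 and 7.61 times that of the control, but with the strict filter the 2-month ratio was 0.289, on the same side as at 1 week. These shares also leave out unnamed clusters of mostly control cells that scored best for this subclass. Interferon-response genes had median log2 ratios of 1.48 and -0.54 in mesenchymal cells and of 1.42 and -0.96 in macrophages. The contractile genes of pericytes and smooth muscle had medians of -0.64 and 0.29, and with the strict filter the 2-month median was -0.10, on the same side as at 1 week. Age differed along with time after surgery, and its part was not tested.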

How the results depend on the processing

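Of the settings tried, 16 were fixed before the data were examined, and 4 were chosen after seeing the data. No paired analysis was possible because each group was 1 library. Where a result moved, the cause was not tested. Share ratios below are against the control, for 1 week and 2 months in that order where 2 are given.

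The contractile median of mesenchymal cells at 1 week ran from 1.74 to 2.33 over 14 settings, the collagen median from 0.97 to 1.39 and the interferon median from 1.31 to 1.61. Wider were the 1-week ranges of the proliferation median, 1.48 to 2.80 in mesenchymal and 1.13 to 2.41 in endothelial cells, of the cartilage-associated median of mesenchymal cells, 1.88 to 3.41, and of the interferon median of macrophages, 0.65 to 1.64. In macrophages at 1 week the resident median ran from -2.28 to -1.87 and the lipid-associated median from 0.85 to 1.02, and the basement membrane median of endothelial cells from 1.25 to 1.63. Endothelial share ratios ran from 0.792 to 0.902 and from 0.645 to 0.684 over 9 settings.

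The lenient filter gave macrophage share ratios of 1.03 and 0.618, a mesenchymal ratio at 2 months of 1.13 and progenitor-like ratios of 0.0683 and 0.540. With the strict filter at 2 months the macrophage ratio was 0.533, the lining-like ratio 1.13 and the Cxcl14 or Clec3b sublining-like ratio 0.289, opposite to the main value. There the contractile median of pericytes and smooth muscle was -0.10, also opposite, and Arhgdib, Matn2 and Fmo2 were higher in the Cxcl14 or Clec3b subclass, with ratios of 2.79, 1.99 and 4.79. Doublets kept gave macrophage ratios of 1.16 and 0.635, a mesenchymal ratio at 1 week of 0.793, a progenitor-like ratio at 2 months of 0.335 and smaller 2-month proliferation medians, 0.16 in mesenchymal and 0.21 in endothelial cells.

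Coarser clusters (resolution 0.5) gave macrophage ratios of 1.11 and 0.636 and progenitor-like ratios of 0.00923 and 0.0433. In macrophages they gave medians of opposite sign for monocyte-derived genes at 1 week (-0.0181) and proliferation genes at 2 months (-0.00138), and Sfrp2 in progenitor-like cells at 2 months had a ratio of 0.243. Finer clusters (resolution 2.0) put both 1-week ratios on the other side of the control, at 1.02 for mesenchymal cells and 0.966 for macrophages. At 2 months these ratios were 1.23 and 0.631, and the lining-like ratios were 0.169 and 0.952. Also with finer clusters the 2-month medians were -0.13 for complement and 0.0858 for proliferation in mesenchymal cells and -0.15 for proliferation in endothelial cells, Hist1h1b in endothelial cells had a ratio of 0.452, and Fmo2 in the Cxcl14 or Clec3b subclass at 1 week one of 1.02.

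Centring and scaling within each library gave macrophage ratios of 1.16 and 0.656, a mesenchymal ratio at 1 week of 0.777, progenitor-like ratios of 0.142 and 0.592 and lining-like ratios of 0.358 and 0.805. The chondrocyte-like ratios were 0.858 and 0.731, opposite to the main values. At 2 months the complement and proliferation medians of mesenchymal cells were -0.18 and 0.0583, and the proliferation median of endothelial cells was -0.14. Ratios at 2 months lay on the other side for Hist1h1b in endothelial cells (0.576), Cilp in progenitor-like cells (1.08), and Cxcl13 and Fmo2 in the Cxcl14 or Clec3b subclass (0.379 and 1.10).

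Subclasses found from control cells alone gave progenitor-like ratios of 0.0775 and 0.642, and subclusters without the list genes gave 0.102 and 0.398. Leaving out the markers as well gave a lining-like ratio at 1 week of 0.180, and leaving bone and marrow types out of the denominator a mesenchymal ratio at 1 week of 0.878. With weights of the control's composition, the 2-month cartilage-associated median of mesenchymal cells was -0.60, opposite to the main value, and the proliferation median 0.23. Equal weight for every cell gave a 2-month complement median of 0.32, opposite to the main value, and medians between the operated libraries of -0.38 for matrix-degrading and 0.44 for adipogenesis genes, both then outside the central 95%. Over 14 settings this matrix-degrading median ran from -0.376 to 0.0457, so its sign is not settled. With no abundance filter the adipogenesis median between the operated libraries was 0.30, and without cells with an Xist UMI 0.26. Without those cells the 2-month complement and proliferation medians were -0.15 and 0.20. Members with at least 200 UMIs gave -0.0292 for complement in mesenchymal and 0.16 for proliferation in endothelial cells at 2 months. Subtracting the mesenchymal profile gave C1qtnf3 in endothelial cells at 1 week a ratio of 0.796, opposite to the main value.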

Other observations

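The tests of free RNA for collagen genes, of a scale shift, of the hour of harvest and of subclass and cluster mix were chosen only after the results were seen. Pericyte and smooth muscle-like cells, the contractile wall of small vessels, held more matrix and interferon transcripts at 1 week (706 cells) than in the control (755 cells), although 85.8% of the control cells lay in 1 cluster and 82.4% of the 1-week cells in another. Free RNA from other cells was not estimated for this class, so its values may include such RNA. Collagen-making genes had a median log2 ratio of 1.87 (percentile 100, 22 of 25 at least 2-fold higher), with Col5a1 at 385 CPM against 22.8, 16.9-fold higher (95% interval 14.1 to 20.2). Basement membrane genes had a median of 1.99 (percentile 100), with Col15a1 85.6-fold higher (54.0 to 145), and interferon-response genes 2.74 (percentile 100, 15 of 15 higher), with Rtp4 18.8-fold higher (11.1 to 34.7). The chemokine gene Ccl2, which draws monocytes, was 7.58-fold higher (6.09 to 9.53) and the cytokine and chemokine list had a median of 1.72 (percentile 100). Proliferation genes had a median of 5.18, with 22 of 23 at least 2-fold higher, although only 3 of 706 cells at 1 week and 0 of 755 in the control lay in a cluster of dividing cells. That count leaves out any dividing cells that stayed in the pericyte clusters. Cycling was the second-scoring class of the cluster that held most 1-week cells of this class. The contractile list lay lower (-0.64, percentile 0.35; its 2-month median had the same sign, -0.10, with the strict filter) with 7 genes at least 2-fold higher and 7 lower. At 2 months (451 cells) collagen-making genes had a median of 0.88, basement membrane genes 0.72 and cytokine and chemokine genes 1.32, each at percentile 100, with Col15a1 12.4-fold (7.68 to 21.3), Ccl2 8.45-fold (6.76 to 10.7) and the lymphoid chemokine gene Ccl19 12.6-fold (9.64 to 16.6) higher. Contractile genes had a median of 0.29 (percentile 99.0), with the smooth muscle actin gene Actg2 at 362 against 44.1 CPM, 8.20-fold higher (7.19 to 9.39), proliferation genes 0.62 (percentile 99.8), and interferon genes -0.38 (percentile 4.42, inside the central 95%). Of 30 lists, 14 lay above and 5 below at 1 week, and 19 above and 3 below at 2 months.

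In the 4 classes of mesenchymal cells, macrophages, endothelial cells and pericytes at once, 142 of 10326 genes were at least 2-fold higher at 1 week and 48 lower, against 18 and 8 of 9751 at 2 months. The higher genes at 1 week included the dividing-cell genes Top2a, Birc5 and Cdk1, the collagen genes Col1a1, Col3a1 and Col5a1, and Postn, Tnc and Mmp14. Free RNA from mesenchymal cells could not account for the cell-cycle genes, since 0% of 57 lay within 3-fold of the level that the free RNA share of 2.49% in macrophages gives, and likewise 0% at the share of 3.29% in endothelial cells. For the collagen genes free RNA is a candidate explanation that stays open, since of the 8 that were not among the markers giving the free RNA share 87.5% lay within 3-fold in macrophages and in endothelial cells, with Col18a1 as the exception, and these are few genes. Of the 85 genes outside the cell cycle, 55.3% in macrophages and 48.2% in endothelial cells lay within 3-fold, among them Postn and Tnc. The other 38 and 44 lay above that level, among them Mmp14 (6.34 and 5.20 times the level) and Il2rg (973 and 544 times). In endothelial cells they also included the macrophage marker gene Ms4a7 (53.9 times), and free RNA from immune cells was not tested. So for the set as a whole free RNA cannot be told apart from expression. A response of several cell types to surgery stays open as untested.

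The clock-output genes Dbp, Tef, Nr1d1 and Nr1d2 were higher in the 2-month library than in the control, with class medians of 0.77 in macrophages, 1.56 in endothelial cells, 2.09 in pericytes and 2.33 in mesenchymal cells, and Dbp 9.57-fold higher (8.68 to 10.6) in mesenchymal cells. At 1 week the same genes went both ways, with Nr1d1 2.81-fold higher in mesenchymal cells, 3.01-fold in endothelial cells and 4.14-fold in pericytes but at a ratio of 0.520 in macrophages, and Dbp at a ratio of 0.747 in mesenchymal cells. A shift of the CPM scale was argued against, since the opposite-phase genes Arntl and Cry1 had a median log2 ratio of -0.87 at 2 months where the 4 genes had 1.96. A clock difference carried only by the mice of 1 sex was argued against by Dbp in mesenchymal cells at 2 months, with a ratio of 0.575 (0.514 to 0.641) between 439 cells with 2 or more Xist UMIs and 5377 without, at 39.1 and 68.1 CPM, both above the control's 6.85. A different hour of harvest may explain the pattern and stays open, because the hour is confounded with the groups, and age and time after surgery stay open as untested.

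As a hypothesis, a different mix of the named subclasses may account for part but not all of the higher contractile and collagen medians of mesenchymal cells at 1 week. Within synovial lining-like cells the contractile list had a median of 1.75 and the collagen list 1.21, both at percentile 100. The lining-like cells of the 2 libraries lay mostly in different clusters, so a mix within this subclass was tested in the 1 cluster with at least 50 cells in both libraries (305 and 62 cells). There the medians were 0.75 and 0.66, smaller but again at percentile 100, which argues against the mix of clusters alone. Other subclasses and free RNA from other mesenchymal cells were not tested and stay open, and no biological explanation was tested.

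Over all kept cells, the ribosome-related transcripts of AY036118 and the mitochondrial tRNA synthetase gene Lars2 were at 185 and 169 CPM in the control, 661 and 146 at 1 week and 867 and 710 at 2 months. Gdpd3 was at 34.8, 48.7 and 3.96 CPM and Hal at 16.3, 8.39 and 0.256 CPM. The stress genes Hspa1a and Fos were at 537 and 3170 CPM in the control, 55.8 and 1283 at 1 week and 113 and 2026 at 2 months.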
